A study of Mus musculus with 3 samples.

How the data were processed

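Lungs of 3 groups of mice were digested with collagenase, and 4 populations were sorted by FACS and mixed in equal amounts for droplet-based 3' RNA sequencing. The gates were CD11c and SigF for alveolar macrophages, CD11b without Ly6G for macrophages, CD3 for T cells (all 3 with CD45), and EPCAM without CD45 for the epithelium. Cells of 3 mice were pooled per library, 1 library per group, with no label that parts the mice. The deposited files hold raw UMI counts per gene and barcode, made by the authors with Cell Ranger on mm10, 32285 genes in each library and no cell filter. Per the submitters' processing notes Cell Ranger 6.0.1 and Seurat 4.0.1 were used, whereas the matrix headers name Cell Ranger 4; the labels name version 2 of the 3' kit, whereas the barcode list is 6794880 long, as in later kits. Values were checked to be whole numbers with no scaling. The aligner's settings are not given in the sources used here.

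Cells were kept from each library alike at a minimum of 1000 UMIs and 500 detected genes and a maximum of 10% of UMIs from mitochondrial genes. The count filters kept 3482, 5020 and 5552 barcodes in WT healthy, WT tumour and PPARg-/- tumour, of which the mitochondrial limit removed 535, 646 and 415 (15.4%, 12.9% and 7.47%). Scrublet, run per library through scanpy at an expected rate of 6%, marked 66, 102 and 146 further barcodes, which were removed. This left 2881, 4272 and 4991 cells. Before doublet removal the 2947, 4374 and 5137 barcodes past the filters held 77.7%, 76.9% and 84.6% of each library's UMIs. Barcodes of 10 to 100 UMIs gave the profile of free RNA in each library.

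Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes were chosen within libraries, leaving out Pparg, Xist, Tsix, Ddx3y, Eif2s3y, Kdm5d and Uty. Leiden clusters (resolution 1.0) were drawn from 30 principal components and 15 neighbours over all 3 libraries together, without integration, so that differences between libraries could part the clusters. Clusters were named by 21 fixed marker sets: a marker counted as raised at 4-fold over the median cluster or more (10 CPM added to both) in at least 10% of cells, and a name needed at least 3 raised markers, thresholds set after the data were seen. Shares in the comparisons were computed only within a lineage, since the mixing of the sorted populations sets the rest. The cells compared as main macrophages are the largest non-cycling cluster with at least 5 of 10 alveolar markers raised in each library, a rule made after the clusters were seen, as the macrophages of each library formed clusters of their own.

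For each class with at least 50 cells in both libraries, UMI counts were summed per library and given as CPM, counts scaled to a total of 1e6, with the log2 ratio of CPM and its exact 95% interval for the ratio of 2 Poisson counts (conditional binomial, Clopper-Pearson). Shares have exact binomial (Clopper-Pearson) intervals. These intervals cover counting error only: with 1 library per group no test between groups was possible, and a difference is given as higher or lower, never as a change. Ratios against 0 UMIs used a floor of 3 counts. Shares of cells with a UMI were taken after each cell was thinned to 1000 UMIs.

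Genes were read in 29 lists. The macrophage and monocyte classes used 21: PPARγ target genes, GM-CSF receptor and STAT5 signalling, alveolar macrophage identity, alternative activation, inflammatory cytokines and NF-kB response, lysosome and phagocytosis, lipid-associated macrophage, EGFR ligands and growth factors, cholesterol biosynthesis, sterol response and uptake, cholesterol efflux and storage, fatty acid uptake and storage, fatty acid oxidation, fatty acid synthesis, glycolysis, oxidative phosphorylation, interferon response, MHC class II and costimulation, MHC class I and antigen processing, proliferation, and dissociation stress as a quality list. Endothelial cells used 13 of these, from cholesterol biosynthesis to dissociation stress in the order given. T cells used the same 13 with the regulatory T cell, checkpoint and exhaustion, cytotoxicity, naive and memory, and type 2 and type 17 lists. AT2 cells used the 13 with the EGFR-MAPK response, surfactant and AT2 identity, and epithelial injury or dedifferentiation lists. The EGFR ligand and the inflammatory lists were read in AT2 cells too. A list's value is the median log2 ratio over members with at least 20 UMIs over both libraries, with a 95% interval from 1000 Poisson resamples and its percentile among 10000 random lists matched on level in 20 bins. Medians stand with that interval after them. A member counted as higher or lower at 1.5-fold or more with an interval that excludes 1, a rule of size and not a test. A member was left open to free RNA where 10% of the free-RNA CPM reached 50% of its class CPM.

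The rule for named genes took Pparg, Csf1r, Csf2, Csf2ra, Csf2rb and Egfr; the 6 highest and 6 lowest ratios in the main macrophages and the 3 highest and 3 lowest in each other class, among genes with at least 50 CPM and 30 UMIs in the higher library and an interval wholly beyond 1.5-fold; and the 2 highest and 2 lowest members of each list. The rankings left out mitochondrial, ribosomal protein, haemoglobin, immunoglobulin, Gm-number and Rik genes. Xist, Tsix, Ddx3y, Eif2s3y, Kdm5d, Uty and genes open to free RNA were left out too. Other list members given as examples were chosen after their values were seen. The filters, lists, markers, named-gene rule, statistics and the alternatives below were fixed before the data were examined. The alternatives were other cell filters (500 UMIs and 250 genes; 2000 UMIs and 1000 genes), mitochondrial limits of 5% and 20%, no doublet removal, Leiden resolutions of 0.5 and 2.0, each library clustered alone, free RNA subtracted, median-of-ratios scaling, the mean of per-cell proportions, thinned cells, all macrophages and monocytes together, and list members with at least 5 UMIs. After the data were seen, a joint class of all clusters with at least 5 alveolar markers, an AT2 class of at least 40 cells and a share that counts cluster 1 among the interstitial macrophages were added. WT healthy interstitial macrophages (39 cells) and AT2 cells (41) lay under the minimum of 50.

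The procedure was tested on simulated data: counts were drawn from the joint profile of the main macrophage clusters of each comparison at their own depths, with 200 genes changed by known folds. In the first comparison 92.0% of 2-fold and 98.0% of 4-fold changes were recovered in the right direction, 0.671% of the unchanged genes among 11503 passed the rule of size, and a list of 10 genes changed 4-fold had a median of 2.01. In the second these values were 90.0%, 99.0%, 0.705% among 12094 genes, and 2.03. The intervals held the true ratio in 95.6% and 95.8% of cases; the simulation carries no variation between mice or libraries. Work was done in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, scikit-learn 1.9.0, leidenalg 0.10.2 and matplotlib 3.10.9; positions are from GENCODE M21 on GRCm38.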

Results

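Single-cell RNA libraries were made from the lungs of mice carrying Ccsp-rtTA and a doxycycline-inducible, lung cancer-associated mutant of EGFR, a transgene pair that drives tumours from the lung epithelium. The 3 groups were WT healthy mice, WT tumour-bearing mice with both Pparg alleles floxed, and PPARg-/- tumour-bearing mice that carried the floxed alleles together with Csf1rCre, which places Cre recombinase in cells of the monocyte and macrophage lineage. Pparg encodes PPARγ, a lipid-activated nuclear receptor required for the maturation of alveolar macrophages. Each group was 1 library pooled from 3 mice of 16 to 20 weeks, all fed doxycycline chow at 625 ppm per the labels, and alveolar macrophages, CD11b+ macrophages, T cells and epithelial cells were sorted and mixed in equal proportion. The series title names another subject, the depletion of KDM4D, NFIB and MLL1 in a mesenchymal cell line. The groups follow the design text and the sample labels. The libraries held 30454790, 46148658 and 44548318 UMIs in the order WT healthy, WT tumour and PPARg-/- tumour, and 2881, 4272 and 4991 cells were kept. Before doublets were removed, the medians were 5667, 4920.5 and 3527 UMIs per cell. With 1 library per group there was no replicate check, and every interval given covers counting error only.

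The gene aimed at by the knockout, Pparg (ENSMUSG00000000440, chromosome 6, 115360951 to 115490399 of GRCm38, plus strand), was read in all 3 libraries. In the main macrophage cluster of each library it stood at 197 CPM in WT healthy, 172 CPM in WT tumour and 376 CPM in PPARg-/- tumour, the last over the WT tumour value by a log2 ratio of 1.13 (95% interval 1.06 to 1.20). In nonclassical monocytes the level was 193, 206 and 181 CPM in the same order, and in classical monocytes 26.8 CPM in PPARg-/- tumour against 36.8 CPM in WT tumour. The kit reads the 3' end of transcripts, and the last of 7 exons of the principal transcript lies at 115489948 to 115490399; the labels do not say which exons are floxed. A transcript that lacks a deleted internal exon can still be counted, so these values check neither the deletion nor its absence.

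Clustering gave 29 clusters, and the macrophages of the 3 libraries fell into separate ones. The largest alveolar-marker cluster held 840 cells in WT healthy (cluster 5), 960 in WT tumour (cluster 2) and 1155 in PPARg-/- tumour (cluster 1), and few cells of any other library apart from 82 PPARg-/- tumour cells in cluster 2. Car4, Spag11b, Ear10 and Fabp4 led cluster 2, Krt79, Acaa1b, Fabp1 and Marco led cluster 5, and Pla2g2d, Ecm1, Apoe, C1qb and Igf1 led cluster 1. These describe the clusters and are not independent results. Of the 10 alveolar macrophage markers, 10, 9 and 7 were raised in clusters 5, 2 and 1, and of the 12 interstitial macrophage markers 2, 1 and 9. The marker rule named clusters 5 and 2 alveolar macrophages and cluster 1 interstitial or monocyte-derived macrophages. A cluster made mostly of 1 library may be that library rather than a cell type, and the rule that set these clusters against each other, the largest non-cycling cluster with at least 5 alveolar markers in each library, was chosen after the data were seen. They are called the main macrophage clusters. Other classes compared were T cells (924, 1365 and 1621), nonclassical monocytes (241, 494 and 1026), classical monocytes (153, 132 and 105), endothelial cells (222, 247 and 387), and, between the tumour libraries alone, interstitial macrophages (182 and 53) and AT2 cells, the surfactant-making alveolar epithelium (188 and 176). Endothelial cells lie outside all 4 sort gates.

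The first comparison, WT tumour over WT healthy, asked how lung macrophages and their neighbours differ when EGFR-mutant tumours are present and Pparg is intact. The labels give the WT healthy mice both transgenes and the same doxycycline chow, and do not say how these mice were kept free of tumours. The grouping thus rests on the word healthy in their label. Egfr in AT2 cells was lower in WT healthy, at 10.3 CPM (3 UMIs in 41 cells) against 59.9 CPM in WT tumour (188 cells). That count does not tell the transgene from the mouse gene and does not show whether tumours were absent. In the main macrophage clusters cholesterol synthesis genes were higher in tumour-bearing lungs: 17 of 19 measured members were at least 1.5-fold higher and 0 lower, with a median log2 ratio of 0.98 (0.92 to 1.11), 1.98-fold. MHC class II genes, which present antigen to CD4 T cells, were also higher, with a median log2 ratio of 1.49 (1.33 to 1.80) and 6 of 9 members up and 1 lower. Interferon-response genes were higher too (3.38, 2.07 to 3.48, 11 of 13), though read at low levels. Inflammatory cytokines and NF-kB response genes were lower, by a median log2 ratio of -1.03 (-1.19 to -0.81), with 8 of 13 lower and 0 higher. In T cells the regulatory T cell genes were higher, 6 of 7, with a median log2 ratio of 1.63 (1.05 to 1.75).

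Among the cholesterol genes, Hmgcs1 (chromosome 13, 119690379 to 119708260), which makes the first committed intermediate of the mevalonate pathway, was read at 159 CPM in WT tumour against 78.4 CPM in WT healthy macrophages, and Sqle (chromosome 15, 59315077 to 59331192), which epoxidises squalene, at 64.0 against 17 CPM in the same order. Idi1, the isopentenyl isomerase, stood at 115 against 36.5 CPM. Ebp and Dhcr7 were the members under 1.5-fold. The cholesterol list lay above all 10000 random lists matched for level (percentile 100). The sterol response and uptake list had a median of 0.51 (0.36 to 0.67), with 3 of 7 higher, among them the sterol carrier Stard4 (48.1 against 15.9 CPM), and 1 lower, the ubiquitin ligase gene Mylip. Fatty acid synthesis was higher as well (0.63, 0.30 to 0.77, 4 of 9), with fatty acid synthase, Fasn, at 38.2 against 11.5 CPM.

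**Figure D1:**
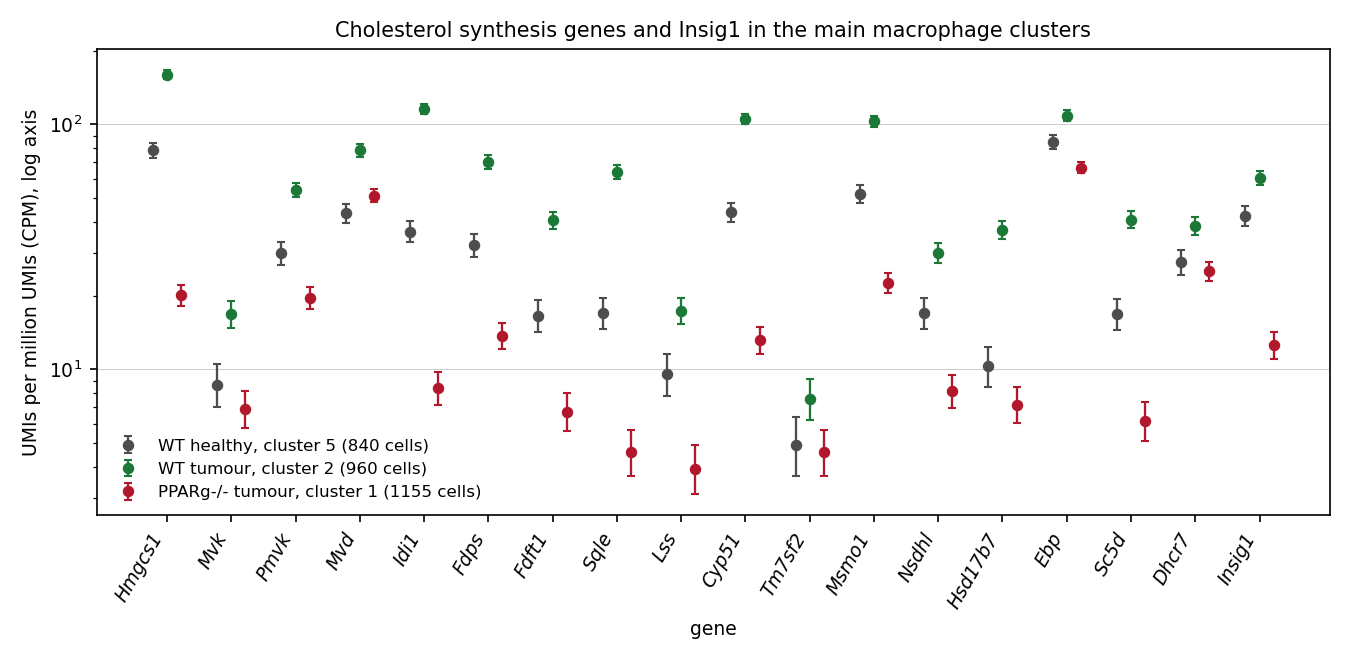
CPM (log axis) of 17 cholesterol synthesis genes and of Insig1 in the main macrophage cluster of each library (840 WT healthy, 960 WT tumour and 1155 PPARg-/- tumour cells, 1 library per group); points are summed counts and bars are exact 95% Poisson intervals, counting error only. Hmgcs1 stood at 78.4, 159 and 20.0 CPM in WT healthy, WT tumour and PPARg-/- tumour.

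Other lipid genes of the macrophages differed in direction from the synthesis genes. Of the PPARγ target genes 7 of 16 were lower in WT tumour and 2 higher, with a median log2 ratio of -0.51 (-0.56 to -0.43). The cholesterol exporter Abca1 was read at 13.9 against 122 CPM and the scavenger receptor Cd36 at 53.3 against 322 CPM, while the fatty acid carrier Fabp5 was higher at 2604 against 512 CPM. Cholesterol efflux and storage (-0.14, 2 higher and 5 lower of 13), fatty acid uptake and storage (-0.09, 3 and 4 of 14) and fatty acid oxidation (-0.05, 0 and 1 of 14) had medians near 0. Genes of lipid-associated macrophages were higher (0.78, 0.76 to 0.82, 5 of 10, 1 lower), with osteopontin, Spp1, at 2235 against 712 CPM and the tetraspanin Cd63 at 595 against 194 CPM. Glycolysis (0.12, 2 of 15 higher, 1 lower) and oxidative phosphorylation (0.26, 0 of 16 past 1.5-fold) differed little. EGFR ligands and growth factors were higher in 4 of 6 members (0.91, 0.61 to 1.33), among them amphiregulin, Areg, at 10.6 against 3.10 CPM.

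Within the MHC class II list, the antigen-presenting chain H2-Eb1 was read at 702 against 15 CPM and the invariant chain Cd74 at 4398 against 924 CPM. The class II transactivator Ciita stood at 33.1 against 11.8 CPM, and the costimulatory ligand Cd86 was lower at 8.11 against 19.3 CPM. MHC class I genes differed less (0.31, 0.24 to 0.40, 4 of 10 higher). The interferon list held the chemokine gene Cxcl9 at 30.4 against 2.91 CPM and Isg15 at 20.4 against 4.73 CPM. Of the inflammatory genes, the chemokine Ccl3 was read at 33.6 against 127 CPM and the monocyte attractant Ccl2 at 1.08 against 9.10 CPM. GM-CSF receptor and STAT5 signalling, the pathway that induces Pparg in alveolar macrophages, was slightly lower (-0.22, -0.31 to -0.15, 3 of 12 lower), with Csf2ra at 237 against 270.3 CPM and Csf2rb at 370.0 against 328 CPM. Lysosome and phagocytosis genes (0.27, 4 of 14 higher) included cathepsin L, Ctsl, at 460.0 against 212 CPM. Alveolar macrophage identity genes, the same genes that picked the clusters, differed little (-0.07, 3 of 10 lower). Proliferation genes, read here in clusters chosen as non-cycling, had a median of -0.09 (1 higher and 2 lower of 16) but -0.93 after thinning. The receptor gene Csf1r, whose promoter drives the Cre, stood at 116 against 222 CPM, while Csf2 and Egfr were at or under 3 UMIs in both.

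Rankings of single genes, here and below, left out Xist, the Y-linked genes and the other kinds that the naming rule excludes. Among the genes ranked, those furthest apart on the higher side were complement C4b (63.9 against 0.273 CPM, log2 ratio 7.87, 6.32 to 10.15), H2-Eb1 (702 against 15 CPM) and Lrg1 (195 against 8.01 CPM). The actin-binding Marcks (66.2 against 4.19 CPM), Wfdc10 (70.2 against 4.64 CPM) and the RNA-binding Igf2bp2 (65.4 against 5.10 CPM) followed. C4b rested on 3 UMIs in WT healthy, and Wfdc10 is among the genes that set the clusters apart. On the lower side stood the oestrogen receptor gene Esr1 (chromosome 10, 4611593 to 5005614) at 0.203 against 99.1 CPM (-8.93, -11.21 to -7.38). With it came the heat-shock genes Hspa1a (5.48 against 146 CPM) and Hspa1b (4.87 against 125 CPM), Acaa1b (16.3 against 348 CPM), Crip1 (19.5 against 351 CPM) and the chemokine Ccl9 (6.22 against 109 CPM). Acaa1b also set the clusters apart. Esr1 was read on 3 UMIs in WT tumour macrophages, and its level in WT healthy was also high in nonclassical monocytes (336 CPM) and classical monocytes (328 CPM) and low in T cells (4.26 CPM).

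Measures of handling and of sex differed between the groups. Genes of the dissociation stress response were lower in WT tumour macrophages (-1.01, -1.06 to -0.96, 10 of 14 lower) and in nonclassical monocytes and T cells (-0.72 and -0.57), in the direction of the inflammatory genes, which respond to handling too. Xist (chromosome X, 103460366 to 103483254), transcribed from the inactive X of females, stood at 1235 CPM over all kept WT healthy cells against 0.177 and 0.305 CPM in WT tumour and PPARg-/- tumour, and the Y-linked Ddx3y at 0.132 against 81.5 and 74.4 CPM. The WT healthy cells thus read as female and those of both tumour libraries as male, whereas the labels state that both sexes were used about equally. The first comparison cannot separate tumour from sex, or from the floxed alleles that the WT healthy genotype lacks.

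The size of several macrophage results depended on the cells compared. The interferon median was 0.54 with each library clustered alone and 0.10 with all macrophages and monocytes together. The MHC class II median ranged over 0.71 to 2.09, and the inflammatory median was -2.61 at a mitochondrial limit of 5%. Alternative activation (1.09, 0.01 to 2.23, 3 of 7 higher, among them the chemokine Ccl17 at 21.7 against 3.37 CPM) turned to -0.25 with each library clustered alone. At the same 5% limit the median of EGFR ligands and growth factors was 0.17, against 1.57 with each library clustered alone. The lipid-associated median was 1.5 at that limit.

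Monocytes differed from the macrophage clusters in their cholesterol genes. In nonclassical monocytes, the vessel-patrolling kind, 4 of 14 cholesterol synthesis genes were lower in WT tumour and 0 higher (-0.41, -0.64 to -0.07). In classical monocytes 6 of 15 were lower (-0.92, -1.20 to -0.42). MHC class II genes were higher in both, 5 of 10 (0.70, 0.38 to 0.80) and 4 of 10 (0.43, 0.30 to 0.72). In nonclassical monocytes the inflammatory list (-0.75, -0.95 to -0.37) and the interferon list (-0.56, 3 of 9 lower) were lower in WT tumour. The genes furthest apart there were Spic, a regulator of iron-recycling macrophages (78.4 against 8.21 CPM), Sh2d1b1 (124 against 16.4 CPM) and the survival gene Bcl2a1d (63.0 against 12.3 CPM), higher, and Esr1 (1.85 against 336 CPM), Atp11b (79.7 against 490.2 CPM) and the heat-shock gene Hsph1 (27.8 against 129 CPM), lower. Classical monocytes had B3gnt8 (69.2 against 17.7 CPM) and the protease inhibitor Timp2 (79.5 against 24.6 CPM) higher, and Esr1 (1.47 against 328 CPM) and Emp1 (7.36 against 58.0 CPM) lower. The other genes named by the rule, Ccl5 and Cxcl9, had 42 of 54 and 240 of 303 UMIs in a single cell. Nonclassical monocytes came mostly from cluster 7 in WT healthy (214 of 241 cells) and from cluster 3 in the tumour libraries (266 of 494 and 729 of 1026).

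T cells of tumour-bearing lungs had more transcripts of regulatory T cell genes. Foxp3, the lineage's defining factor, was read at 28.1 against 9.05 CPM, Ikzf2, which encodes Helios, at 191 against 61.5 CPM and the costimulatory receptor Tnfrsf4 at 55.8 against 12.0 CPM, while Icos stood at 93.5 against 103 CPM. A single WT tumour cell held 47 of that library's 248 Tnfrsf4 UMIs. After each cell was thinned to 1000 UMIs, a Foxp3 UMI was found in 2.49% of WT tumour T cells and 0.649% of WT healthy ones, and in 0 of the main macrophages. Checkpoint and exhaustion genes were mixed (0.48, 0.33 to 0.78, 4 higher and 3 lower of 11), with Pdcd1, which encodes PD-1, higher at 19.6 against 3.99 CPM and the early-response receptor gene Nr4a3 lower at 14.6 against 53.0 CPM. Cytotoxicity (0.07, 3 higher and 2 lower of 10), naive and memory genes (-0.23, 0 of 8 past 1.5-fold) and type 2 and type 17 genes (-0.14, 1 of 3 higher) differed less. The genes furthest apart were the proteasome adaptor Ecpas (52.2 against 6.66 CPM), Tnfrsf4 and Ikzf2, higher, and Gdpd3 (2.25 against 82.6 CPM), Hsph1 (43.2 against 160.1 CPM) and Nr4a3, lower. Clusters low in naive and memory genes held 20.9% of T cells in WT healthy (18.3% to 23.7%; 193 of 924), 37.7% in WT tumour (35.1% to 40.3%; 514 of 1365) and 28.9% in PPARg-/- tumour (26.7% to 31.2%; 469 of 1621), a split chosen after the data were seen. With each library clustered alone WT healthy stood at 40.6% and above both tumour libraries. At Leiden resolution 2.0 the tumour libraries stood level, at 51.1% in WT tumour and 50.8% in PPARg-/- tumour against 27.9% in WT healthy.

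**Figure D2:**
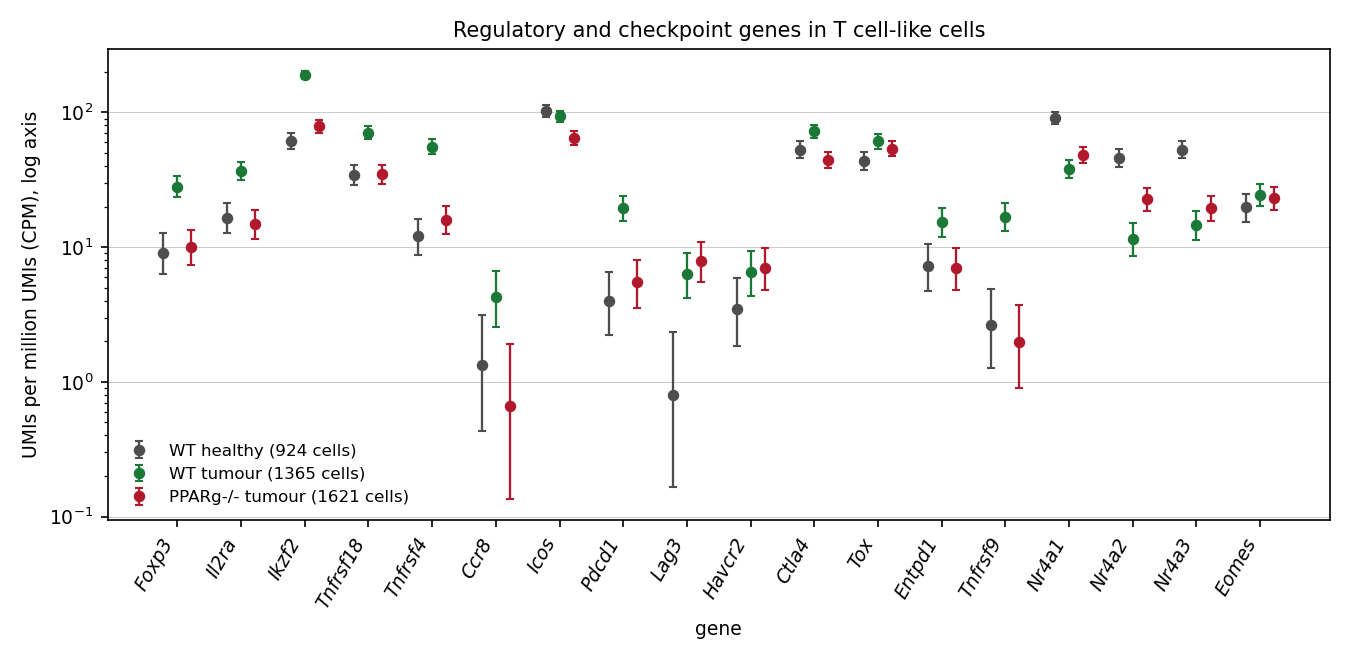
CPM (log axis) of 18 regulatory T cell and checkpoint genes in the T cells of each library (924 WT healthy, 1365 WT tumour and 1621 PPARg-/- tumour cells, 1 library per group); points are summed counts and bars exact 95% Poisson intervals, counting error only. Foxp3 stood at 9.05, 28.1 and 10.1 CPM in WT healthy, WT tumour and PPARg-/- tumour.

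Endothelial cells of WT tumour lungs were higher in glycolysis genes (0.78, 0.62 to 0.99, 8 of 13 higher), with lactate dehydrogenase A, Ldha, at 302 against 104 CPM, and in MHC class II genes (1.20, 7 of 8). Ankrd37, a hypoxia-responsive gene, was read at 309.7 against 16.3 CPM and the neurotrophin receptor Ntrk2 at 699.8 against 58.3 CPM. Scgb3a1, a club or secretory epithelial marker, stood at 57.1 against 2.87 CPM, on 64 UMIs in 20 of 247 WT tumour cells. Whether its counts come from endothelial cells was not tested. Lipg and Gucy1a1, which the rule also named, lead a small cluster that was named endothelial but holds Pdgfrb and other genes of pericytes (6 cells in WT healthy, 0 in WT tumour and 2 in PPARg-/- tumour), so their ratios are not given as a difference within endothelial cells; the class was not compared without that cluster. Gzma was lower in WT tumour, but 101 of its 103 UMIs in WT healthy lay in a single cell. AT2 cells could be compared only with the minimum lowered to 40 cells, a setting added after the data were seen, since WT healthy held 41. There, genes of epithelial injury were higher in WT tumour (1.17, 5 of 8, 1 lower), as was the EGFR-MAPK response (0.35, 4 of 15), and cholesterol synthesis genes were lower (-0.80, 6 of 18). Of the proliferation genes 12 of 17 were higher, most of them against 0 or 1 UMI in WT healthy, so the size of that difference was not measured.

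**Figure D3:**
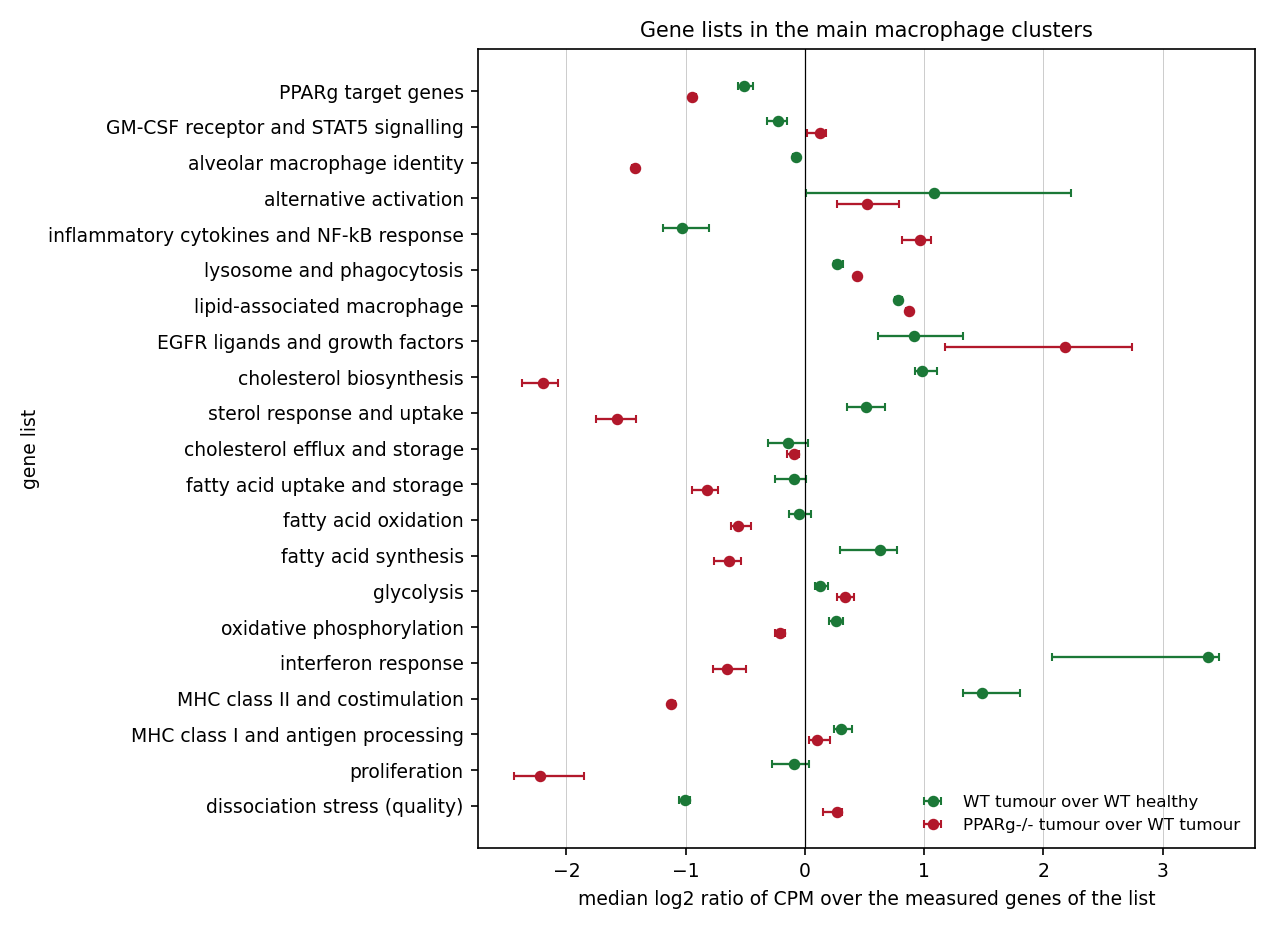
Median log2 CPM ratio of 21 gene lists in the main macrophage clusters, WT tumour over WT healthy and PPARg-/- tumour over WT tumour (1 library per group); bars are 95% intervals from resampled Poisson counts, counting error only. Cholesterol synthesis stood at 0.98 in the first comparison and -2.20 in the other.

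The second comparison, PPARg-/- tumour over WT tumour, asked what differs in tumour-bearing lungs when the floxed Pparg alleles come together with Csf1rCre. The Pparg counts above check neither the deletion nor its absence. The main macrophage cluster of the PPARg-/- lungs was far lower in cholesterol synthesis genes: all 19 measured members were at least 1.5-fold lower, with a median log2 ratio of -2.20 (-2.37 to -2.07), 4.58-fold lower. PPARγ target genes were lower, 10 of 15 against 2 higher, with a median of -0.95 (-0.97 to -0.91), and so were MHC class II genes (-1.12, -1.14 to -1.09, 6 of 10, 2 higher). Genes of lipid-associated macrophages were higher by median (0.88, 0.85 to 0.90), with 6 of 10 higher and 3, Fabp5, Lpl and Cd9, lower. That list shares Trem2 and Apoe with the interstitial macrophage markers that served to name the clusters. In T cells the regulatory T cell genes were lower, 6 of 7, with a median of -1.31 (-1.58 to -1.15).

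Hmgcs1 was read at 20.0 against 159 CPM, Sqle at 4.59 against 64.0 CPM and Idi1 at 8.42 against 115 CPM in PPARg-/- tumour against WT tumour macrophages. Stard4 stood at 4.39 against 48.1 CPM and Insig1, which retains the sterol-sensing complex in the endoplasmic reticulum, at 12.6 against 60.4 CPM. The sterol list had a median of -1.58 (-1.75 to -1.42), with 4 of 7 lower and 1, Mylip (60.8 against 22.9 CPM), higher. Among the PPARγ targets Nr1h3, which encodes the sterol sensor LXRα, was read at 6.48 against 39.4 CPM, the oxidised-LDL receptor Olr1 at 96.1 against 418 CPM and Abca1, against the direction of the list, at 265 against 13.9 CPM. A shift common to the genes lay under these values: the median over 2505 genes with at least 50 CPM was -0.20. Relative to it the cholesterol median was -2.0 (15 of 19 lower), the PPARγ target median -0.75 and the MHC class II median -0.92.

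The remaining lipid lists of the macrophages were lower or mixed. Fatty acid uptake and storage had a median of -0.82 (-0.62 relative to the shift, 9 lower and 1 higher of 14), fatty acid oxidation -0.56 (-0.36, 7 and 0 of 14) and fatty acid synthesis -0.63 (-0.44, 5 and 2 of 9), the elongase Elovl6 at 2.14 against 36.1 CPM. Cholesterol efflux and storage was mixed (-0.09, 5 higher and 4 lower of 13). Glycolysis was slightly higher (0.34, 5 higher and 1 lower of 15), with hexokinase 2, Hk2, at 210.1 against 100.1 CPM, and oxidative phosphorylation -0.21 (-0.01 relative to the shift). Of the lipid-associated genes the phagocytic receptor Trem2, also an interstitial marker, was read at 585 against 119 CPM and Spp1 at 5208 against 2235 CPM. Lysosome and phagocytosis genes (0.44, 4 of 14 higher) were slightly higher, while the efferocytosis receptor Mertk was lower at 122 against 264 CPM.

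Immune genes of the macrophages also differed. H2-Aa stood at 618 against 1460.3 CPM and Ciita at 10.9 against 33.1 CPM, against Cd86, which was higher at 56.6 against 8.11 CPM. Inflammatory genes were higher (0.97, 0.82 to 1.06, 9 of 14, 2 lower), with Ccl2 at 29.5 against 1.08 CPM. Interferon-response genes had a median of -0.66 (8 of 13 lower, 3 higher) and MHC class I genes 0.10. EGFR ligands and growth factors were higher, 7 of 9 (2.18, 1.18 to 2.74), with the platelet-derived growth factor chain Pdgfb at 65.2 against 3.85 CPM and hepatocyte growth factor, Hgf, at 48.0 against 23.0 CPM. Proliferation genes were lower (-2.22, 13 of 16), with a median of -0.82 after thinning and with free RNA left open as the source of 7 of them. The main clusters were chosen as non-cycling, and cycling alveolar macrophages lay in a cluster of their own (45, 83 and 20 cells in WT healthy, WT tumour and PPARg-/- tumour), so this list does not measure macrophage proliferation as a whole. GM-CSF receptor and STAT5 signalling genes were mixed (0.12, 2 higher and 2 lower of 12), with Csf2ra at 265 against 237 CPM and Csf2rb at 265 against 370.0 CPM. Csf1r, also one of the interstitial macrophage markers, was higher at 315 against 116 CPM. The dissociation stress list was slightly higher (0.27, 3 higher and 3 lower of 14), with Hspa1a at 108 against 5.48 CPM.

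The 2 clusters also differed in the genes that tell macrophage types apart. Alveolar macrophage identity genes, which served to pick the clusters, were lower in 8 of 10 members (-1.43, -1.23 relative to the shift), with the alveolar macrophage lectin Siglecf at 6.84 against 134 CPM. The genes furthest apart were the matrix protease Mmp2 (80.5 against 0.0676 CPM; log2 ratio 10.22, 7.74 to 15.52, on 1 UMI in WT tumour), the lipoprotein Apoe (13706 against 12.0 CPM), the complement genes C1qc (1109 against 1.56 CPM), C1qa (1887 against 3.11 CPM) and C1qb (1934 against 4.26 CPM) and Ecm1 (795 against 1.35 CPM), higher. On the lower side stood the scavenger receptor Marco (0.255 against 328 CPM), Wfdc10 (0.102 against 70.2 CPM), Spag11b (0.204 against 116 CPM), the short-chain fatty acid receptor Ffar2 (0.255 against 101 CPM) and Prom1 (0.255 against 69.6 CPM). The serotonin receptor Htr2c, with 0 against 785 UMIs, was lower by a log2 ratio of -8.44 or beyond at the floor of 3 counts. Apoe, C1qb, Ecm1, Marco, Wfdc10, Spag11b and Ffar2 are among the genes that define the clusters and are given as such. C1qa and C1qc, like Apoe and C1qb, belong to the interstitial macrophage markers by which cluster 1 was named, so their ratios are not independent of that name. The comparison thus set clusters of differing macrophage identity against each other, and cannot separate a difference within 1 cell type from a difference in cell type.

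Several of these macrophage values turned with the clustering. At a Leiden resolution of 2.0 and with each library clustered alone, the inflammatory median was -0.14 and -0.33 and that of interferon response 0.28 and -0.32. Alternative activation (0.52, 0.27 to 0.79, 4 of 8 higher, 2 lower) stood at -1.19 and -0.71 in the same order. EGFR ligands and growth factors stood at 1.1 and 0.51, and MHC class II at -2.62 and -2.52. Alveolar identity stood at -2.15 with each library clustered alone and the sterol list at -0.96 with all macrophages and monocytes together. The cholesterol and PPARγ target medians stayed within -2.49 to -1.71 and -0.98 to -0.75 under all alternatives. Both comparisons share the WT tumour library; with its cells split at random between them, the cholesterol medians were 1.04 and -2.24 and the PPARγ target medians -0.54 and -0.95. The interferon median of the second comparison shrank in that split to -0.22 (-0.57 to -0.0027, 4 lower and 3 higher of 13). PPARg-/- tumour over WT healthy, without the WT tumour library, gave -1.21 for cholesterol synthesis (13 of 19 lower) and -1.43 for the PPARγ targets.

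T cells of PPARg-/- lungs had fewer transcripts of regulatory T cell genes: Foxp3 was read at 10.1 against 28.1 CPM, Ikzf2 at 78.6 against 191 CPM and Tnfrsf4 at 16.0 against 55.8 CPM. Of the 248 WT tumour UMIs of Tnfrsf4, 47 lay in a single cell. A Foxp3 UMI was found in 0.864% of PPARg-/- T cells and 2.49% of WT tumour ones after thinning. Of the checkpoint genes 4 of 11 were lower and 1 higher (-0.08), Pdcd1 at 5.47 against 19.6 CPM and the costimulatory receptor Tnfrsf9 at 1.97 against 16.9 CPM. Cytotoxicity genes were higher in 3 of 10 (0.50, 0.33 to 0.60), with granzyme A, Gzma, at 237 against 99.6 CPM, but with each library clustered alone the median turned to -1.07 and the log2 ratio of Gzma from 1.25 to -3.77. Naive and memory genes (0.09, 0 of 8 past 1.5-fold) and the dissociation stress list (0.11) differed little. Type 2 and type 17 genes were lower in 2 of 3 (-0.65), and proliferation genes in 13 of 17 (-1.21, -1.76 to -1.01; -0.32 after thinning). The genes furthest apart on the higher side were the chemokine Ccl4 (93.9 against 22.3 CPM), the interferon-induced Gbp8 (54.7 against 16.4 CPM) and Gzma. Ccl4 turned as Gzma did, and 94 of its 429 PPARg-/- UMIs lay in a single cell. Tnfrsf4, the proprotein convertase Furin (21.9 against 74.2 CPM) and Ms4a6c (20.1 against 54.0 CPM) were furthest apart on the lower side.

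AT2 cells, of the epithelium in which the mutant EGFR is induced, differed little in the EGFR-MAPK response between the tumour libraries: 0 of 16 members counted as higher or lower by the rule of size and the median was -0.25 (-0.33 to -0.04), or -0.13 relative to a shift of -0.12 over 2602 genes. Egfr itself was read at 44.1 against 59.9 CPM (-0.44, -0.79 to -0.10; 0.51 after thinning), a count that does not tell the transgene from the mouse gene. EGFR ligands and growth factors were lower in 4 of 7 members (-0.77, -1.01 to -0.49). Among them were the ligands Areg (93.9 against 206 CPM) and Hbegf (45.6 against 88.6 CPM) and the growth factor Vegfa (68.1 against 116 CPM). Surfactant and AT2 identity (0.09, 1 of 12 higher), epithelial injury or dedifferentiation (-0.11, 1 higher and 1 lower of 10) and inflammatory genes (-0.14) differed little, with surfactant protein C, Sftpc, at 147453 against 124273 CPM. Cholesterol synthesis genes were higher in PPARg-/- AT2 cells (0.54, 0.43 to 0.80, 8 of 19), the isoprenoid synthase Fdps at 112 against 53.5 CPM. Proliferation genes were lower (-1.04, 11 of 17). At a mitochondrial limit of 5% the proliferation median turned to 0.51 and the medians of injury, surfactant and inflammatory genes were -1.59, 0.76 and -0.91. That of EGFR ligands and growth factors was -1.38 at the same limit. The lipid carrier Fabp5 (1104 against 279 CPM) was among the genes furthest apart, with S100a6 (80.1 against 235 CPM) and Thbs1 (29.2 against 74.8 CPM) on the lower side. Of the 222 WT tumour UMIs of Thbs1, 46 lay in a single cell. Single cells held 214 of 216 UMIs of Bpifa1, 246 of 447 of Dlk1 and 138 of 277 of Retnla, the others named by the rule.

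In the other myeloid cells of PPARg-/- lungs the cholesterol synthesis genes were not lower by median, at 0.12 in nonclassical monocytes, 0.02 in classical monocytes and 0.36 in interstitial macrophages. In nonclassical monocytes inflammatory genes were higher (0.74, 0.63 to 0.92, 6 of 10), while 4 of 12 PPARγ targets were lower and 2 higher (-0.20), the lipid-droplet protein Plin2 at 96.6 against 400.2 CPM. The medium-chain fatty acid receptor gene Gpr84 (61.2 against 8.03 CPM), Wnt6 (86.2 against 11.7 CPM) and the membrane protease Mmp14 (92.2 against 13 CPM) were higher, and transferrin, Trf (23.9 against 243 CPM), the antibody receptor Fcgrt (8.98 against 72.3 CPM) and Ccl9 (37.3 against 165 CPM) lower. Classical monocytes had MHC class II genes lower (-0.61, -0.70 to -0.48, 6 of 9), a median that turned to 0.14 with each library clustered alone. The death receptor Fas (101 against 17.7 CPM), Fpr2, a receptor for formyl peptides (227 against 48.6 CPM), and Ifi206 (87.9 against 23.6 CPM) were higher in these cells. Lower were Thbs1 (7.64 against 61.9 CPM), with 9 of 42 WT tumour UMIs in a single cell, and Ifi202b (0 against 58 UMIs). In interstitial macrophages, on 53 PPARg-/- cells, PPARγ targets (-0.77, -1.09 to -0.43, 4 of 10), inflammatory genes (-0.70, -1.01 to -0.42, 5 of 12, 1 higher; -1.48 after thinning) and lipid-associated genes (-0.68, -0.93 to -0.35, 4 of 10) were lower. The B cell attractant Cxcl13 (504 against 80.3 CPM) and lymphotoxin beta, Ltb (111 against 17.9 CPM), were higher there, with 49 of 150 and 11 of 33 UMIs in a single cell, and Cxcl2 (87.3 against 711 CPM) lower. In single cells lay 1018 of 1028 UMIs of Scgb1a1, 985 of 1728 of Retnla and 36 of 74 of Gdf15, which the rule also named.

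Endothelial cells of PPARg-/- lungs were lower in glycolysis genes (-0.53, -0.72 to -0.38, 5 of 13), with Ankrd37 at 35.9 against 309.7 CPM, and in the dissociation stress list (-0.57, 7 of 14), with the immediate-early gene Fos at 15.4 against 182 CPM. Interferon-response genes were higher in 4 of 13 (0.49). The anchoring protein Akap5 (74.6 against 16.1 CPM) was among the genes furthest apart, and Pde5a, also named by the rule, is a leading gene of the small pericyte-marked cluster and had 40 of 139 UMIs in a single cell. Single cells held all 219 WT tumour UMIs of Ccl21a and 47 of 100 PPARg-/- UMIs of Gucy1a1. By share, nonclassical monocytes made up 86.7% (84.6% to 88.5%; 1026 of 1184) of monocytes and interstitial macrophages in PPARg-/- tumour, 61.1% (57.7% to 64.5%; 494 of 808) in WT tumour and 55.7% (50.8% to 60.4%; 241 of 433) in WT healthy. These shares leave out cluster 1, the main macrophages of PPARg-/- tumour, which the marker rule named interstitial or monocyte-derived. With it counted, PPARg-/- tumour stood at 43.9% (41.8% to 45.9%; 1026 of 2339), below WT tumour at 60.5% and WT healthy at 55.0%, so the direction rests on how that cluster is named. AT1 cells, the flat gas-exchange epithelium, made up 16.0% (11.6% to 21.3%; 38 of 237), 38.6% (33.7% to 43.7%; 148 of 383) and 12.1% (4.99% to 23.3%; 7 of 58) of epithelial cells in the same order. With a minimum of 2000 UMIs the WT tumour share was 24.0%, and at a mitochondrial limit of 5% PPARg-/- tumour stood at 26.7% and WT healthy at 38.5%.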

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

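The tests of a library-wide difference and of the Pparg genotype for the cholesterol genes, of mixtures for the 82 cells, and all 3 tests for Esr1 were chosen only after the result was seen.

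Some lists differed in opposite directions between cell classes under the same comparison, and these differences between classes were not tested. PPARg-/- tumour over WT tumour gave a median log2 ratio of 2.18 for EGFR ligands and growth factors in the main macrophages and -0.77 in AT2 cells. Inflammatory genes gave 0.97 in the main macrophages and 0.74 in nonclassical monocytes, against -0.70 in interstitial macrophages, but the main macrophage value turned to -0.14 at Leiden resolution 2.0, -0.33 with each library clustered alone and -0.36 at a minimum of 2000 UMIs, the direction of the interstitial macrophages. Lipid-associated genes gave 0.88 in the main macrophages and -0.68 in interstitial macrophages. WT tumour over WT healthy gave 1.09 for alternative activation in the main macrophages and -1.01 in classical monocytes. The former turned to -0.11 after thinning and at a mitochondrial limit of 5%, -0.25 with each library clustered alone and -0.068 with free RNA subtracted, and the latter to 0.019 at a mitochondrial limit of 20%. Cholesterol biosynthesis gave 0.98 against -0.92 in the same 2 classes. In cells outside the comparisons, an unnamed cluster, led by Mgl2, Cd209a, Ccl17 and H2-Eb1, held 5.38% of WT tumour cells against 3.02% of WT healthy and 1.48% of PPARg-/- tumour ones. These are shares of all kept cells, which the mixing of the sorted populations sets in part.

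Cholesterol genes were lower in the PPARg-/- macrophage cluster than in that of WT tumour, and 3 explanations were weighed. A difference that reached every cell class of the libraries was argued against, since the lowest median among nonclassical monocytes, classical monocytes, T cells and endothelial cells was -0.19. Macrophages of another type could account for part of it: in WT tumour itself, with Pparg intact, interstitial macrophages had a median of -1.66 (-1.95 to -1.25) against the alveolar-marker cluster. The Pparg genotype of the macrophages cannot be told apart from this, because genotype and library coincide, although the median was -1.71 or lower under all alternatives. Cluster and library do not wholly coincide: within the WT tumour cluster, 82 PPARg-/- cells were lower than the WT tumour cells beside them by -1.02 (-1.27 to -0.81, 14 of 19 lower), which leaves a difference of library or genotype open beside that of macrophage type. Whether loss of Pparg in 1 cell type lowers these genes stays an untested hypothesis.

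A group of 82 PPARg-/- tumour cells lay inside the WT tumour macrophage cluster. Barcodes carried over from the WT tumour library were argued against, as 0 of the 82 were shared with its kept cells, an upper limit of 4.4%. Mixtures with a cell of the PPARg-/- cluster were argued against for these cells. Their C1qa, C1qb, C1qc and Apoe stood at a median of 0.629% of that cluster's CPM. Apoe and C1qb are among the genes that set the clusters apart, so placement by expression itself favours low values here. The value speaks only for the 82 cells as placed. Macrophages in which Pparg was not deleted may explain them, and their PPARγ target median over the WT tumour cells of the cluster was -0.21, but cells placed by expression must resemble that cluster, so this test decides nothing and the explanation stays open.

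Esr1 was read in myeloid cells of WT healthy, at 336 CPM in nonclassical monocytes and 99.1 CPM in the main macrophages, and hardly in either tumour library. Free RNA was argued against, as the higher of T cell and endothelial Esr1 stood at 1.27% of the nonclassical monocyte level in the same library. Sex possibly matters, but it is confounded with the group: Xist was at most 0.305 CPM in the tumour libraries. Esr1 sequence within a transgene under Csf1r control, such as an oestrogen receptor-fused Cre, could also give such counts. The ratio of Esr1 to Csf1r spread 4.5-fold over the myeloid classes, 0.0990 to 0.446. The low end came from the interstitial macrophages alone, on 31 Esr1 UMIs in 39 cells. The other myeloid classes lay at 0.263 to 0.446. Neither these ratios nor the labels decide whether such a transgene was present.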

How the results depend on the processing

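The tests that joined all alveolar-marker clusters, lowered the AT2 minimum to 40 cells or counted cluster 1 among the interstitial macrophages were chosen only after the result was seen. The lead list medians and the Pparg ratio kept their direction under the alternatives run for them. The lead lists are a chosen set: those that open each comparison, and the EGFR-MAPK response in AT2 cells. Lists outside that set did turn, among them the inflammatory and interferon lists of the main macrophages in the second comparison. Cholesterol genes ranged over 0.78 to 1.13 in the first comparison, and regulatory T cell genes over 1.19 to 1.68 and -1.52 to -1.09 in the 2 comparisons. The second comparison gave -2.49 to -1.71 for cholesterol, -0.98 to -0.75 for PPARγ targets, -2.62 to -0.92 for MHC class II and 0.73 to 1.36 for lipid-associated genes. It gave -0.29 to -0.0012 for the EGFR-MAPK response in AT2 cells and 0.89 to 1.33 for Pparg. The order of the groups by share of nonclassical monocytes, of low-naive T cells and of AT1 cells turned under some alternatives. In the first comparison the interferon median ranged over 0.10 to 3.70, MHC class II over 0.71 to 2.09 and inflammatory genes over -2.61 to -0.68. Of 674 alternative values for 50 list medians beyond 1.5-fold, each a list in 1 class and 1 comparison, 659 kept their direction. For 140 named gene ratios beyond 1.5-fold, 1803 of 1812 alternative values did. Both sets were taken for their large ratios, and the alternatives reuse the same libraries and largely the same cells. Kept directions were therefore likely from the start, and these counts say nothing about other mice. Of all 151 named gene ratios, 100 moved by more than 1.5-fold under some alternative, and genes with few UMIs in 1 group are limited by depth. No paired analysis was possible because the mice were pooled, and with 1 library per group none could be left out. AT2 and interstitial macrophage results rest on few cells, some alternatives left a class under 50 cells and gave no value, and the doublet calls were not used for WT healthy at the 5% limit, where they marked 0.437%.

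Values are median log2 ratios in the main macrophages unless another class or a gene is named, and the cause of these differences was not tested. Each cell thinned to 1000 UMIs gave 1.61 for interferon and 2.09 for MHC class II in the first comparison. It also turned the sign to -0.11 for alternative activation in the first comparison. In the second comparison each cell thinned to 1000 UMIs gave 0.89 for Pparg, -0.91 for PPARγ targets, 0.73 for lipid-associated genes, -1.21 for MHC class II, -1.09 for regulatory T cell genes and -0.0012 for EGFR-MAPK. Leiden resolution 0.5 gave -1.88 for inflammatory genes in the first comparison. Leiden resolution 0.5 put the low-naive share of T cells at 17.2% in WT healthy, 33.1% in WT tumour and 25.7% in PPARg-/- tumour, the nonclassical share at 46.4% in WT healthy, 47.6% in WT tumour and 82.3% in PPARg-/- tumour and the AT1 share at 46% in WT tumour. Leiden resolution 2.0 gave 1.77 for interferon in the first comparison. For the second comparison Leiden resolution 2.0 gave 1.23 for Pparg, -0.79 for PPARγ targets, 1.36 for lipid-associated genes and -2.62 for MHC class II. That setting turned the sign to -0.14 for inflammatory genes, 0.28 for interferon and 0.14 for proliferation in interstitial macrophages. Leiden resolution 2.0 put the low-naive share of T cells at 27.9% in WT healthy, 51.1% in WT tumour and 50.8% in PPARg-/- tumour. Each library clustered alone gave -0.68 for inflammatory genes, 1.13 for cholesterol, 0.54 for interferon and 0.71 for MHC class II in the first comparison. It also turned the sign to -0.25 for alternative activation and -0.17 for Ccl5 in classical monocytes in the first comparison. Between the tumour libraries each library clustered alone gave 1.24 for Pparg, -0.84 for PPARγ targets, 1.24 for lipid-associated genes and -2.52 for MHC class II. That setting turned the sign to -0.33 for inflammatory genes, -0.24 for alternative activation in classical monocytes, 0.14 for MHC class II in classical monocytes, -0.18 for Ccl4 in T cells, -3.77 for Gzma in T cells and 0.13 for Retnla in AT2 cells. Each library clustered alone put the low-naive share of T cells at 40.6% in WT healthy, 35.0% in WT tumour and 19.2% in PPARg-/- tumour, the nonclassical share at 46.4% in WT healthy and the AT1 share at 0% in WT healthy. A minimum of 500 UMIs and 250 genes gave 3.51 for interferon in the first comparison. It also turned the sign to -0.42 for Ccl5 in classical monocytes in the first comparison. A minimum of 2000 UMIs and 1000 genes gave -1.25 for inflammatory genes in the first comparison. In the second comparison a minimum of 2000 UMIs and 1000 genes gave 1.25 for Pparg, -0.82 for PPARγ targets, 1.36 for lipid-associated genes and -2.45 for MHC class II. That setting turned the sign to -0.36 for inflammatory genes and -0.43 for Scgb1a1 in interstitial macrophages. A minimum of 2000 UMIs and 1000 genes put the nonclassical share at 53.9% in WT tumour and 83.6% in PPARg-/- tumour and the AT1 share at 24.0% in WT tumour. A mitochondrial limit of 5% gave -2.61 for inflammatory genes, 1.57 for interferon and 1.28 for MHC class II in the first comparison. It also turned the sign to -0.11 for alternative activation in the first comparison. For the second comparison a mitochondrial limit of 5% gave -0.81 for PPARγ targets, 1.21 for lipid-associated genes, -2.49 for cholesterol and -1.67 for MHC class II. That setting turned the sign to -0.37 for Bpifa1 in AT2 cells, 0.73 for Retnla in AT2 cells, 0.51 for proliferation in AT2 cells and 0.29 for Ccl21a in endothelial cells. A mitochondrial limit of 5% put the low-naive share of T cells at 17.7% in WT healthy and 32.3% in PPARg-/- tumour, the nonclassical share at 64.9% in WT tumour and 88.7% in PPARg-/- tumour and the AT1 share at 38.5% in WT healthy and 26.7% in PPARg-/- tumour. Free RNA subtracted gave -1.34 for inflammatory genes and 3.70 for interferon in the first comparison. It also turned the sign to -0.068 for alternative activation in the first comparison. Between the tumour libraries free RNA subtracted gave -1.18 for MHC class II. All macrophages and monocytes together gave -1.47 for inflammatory genes, 0.78 for cholesterol, 0.10 for interferon and 1.20 for MHC class II in the first comparison. In the second comparison all macrophages and monocytes together gave -0.85 for PPARγ targets, 0.85 for lipid-associated genes, -1.71 for cholesterol and -1.21 for MHC class II. All alveolar-marker clusters together gave -1.83 for inflammatory genes, 0.90 for cholesterol and 2.03 for interferon in the first comparison. For the second comparison all alveolar-marker clusters together gave -0.87 for PPARγ targets, -2.04 for cholesterol and -0.97 for MHC class II. A mitochondrial limit of 20% turned the sign to 0.019 for alternative activation in classical monocytes in the first comparison. Between the tumour libraries a mitochondrial limit of 20% gave -1.08 for MHC class II. That setting turned the sign to -1.07 for alternative activation in classical monocytes. A mitochondrial limit of 20% put the nonclassical share at 49.5% in WT healthy and 57.0% in WT tumour. Median-of-ratios scaling gave 1.33 for Pparg, -0.75 for PPARγ targets, 1.07 for lipid-associated genes, -2.0 for cholesterol and -0.92 for MHC class II in the second comparison. The mean of per-cell proportions gave -0.91 for PPARγ targets, 0.77 for lipid-associated genes and -1.08 for MHC class II in the second comparison. List members with at least 5 UMIs gave -0.98 for PPARγ targets. That setting turned the sign to -0.030 for alternative activation in classical monocytes in the second comparison. No doublet removal put the low-naive share of T cells at 18.3% in WT healthy. Counting cluster 1 among the interstitial macrophages put the nonclassical share at 43.9% in PPARg-/- tumour.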

Other observations

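The tests reported in this part were all chosen after the main comparisons were seen.

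The 82 PPARg-/- tumour cells inside the WT tumour macrophage cluster were compared with both main macrophage clusters. Against the WT tumour cells beside them, cholesterol synthesis genes were lower, 14 of their measured members, with a median log2 ratio of -1.02, while proliferation genes (0.74), interferon-response genes (0.63) and MHC class II genes (0.54) were higher. Against the PPARg-/- macrophage cluster of their own library, cholesterol synthesis was higher at 1.19, MHC class II at 1.61 and PPARγ targets at 0.83. The cholesterol genes of these cells thus stood between the 2 clusters, apart from the WT tumour cells of their own cluster and from the other cluster of their own library by about as much, and clusters are drawn from expression.

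PPARg-/- tumour was also set directly against WT healthy. In the main macrophages lipid-associated genes were higher (2.02), as were EGFR ligands and growth factors (2.05), interferon-response genes (2.10) and MHC class II genes (0.86). Alveolar macrophage identity genes, which served to pick the clusters, were lower (-1.52, 7 of 10), so clusters of differing macrophage identity were compared here too. Proliferation genes, read in clusters chosen as non-cycling, were also lower (-2.35, 15 of 16). The dissociation stress list was lower (-0.94, 9 of 14), and the 2 libraries differed in sex as read from Xist. Regulatory T cell genes stood at 0.08 in T cells, between libraries that by label differ in both tumour and genotype. Interleukin 10, Il10, an anti-inflammatory cytokine, was read at 48.4 CPM in PPARg-/- nonclassical monocytes against 4.94 CPM in WT tumour ones.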
